A study of Mus musculus with 8 samples.

How the data were processed

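Native chromatin immunoprecipitation with a customized H2A.X antibody was followed by single-molecule real-time sequencing of the DNA of TT2 ES cells, WT or with a KO of Alkbh1. Per the labels, each of the 8 samples was 1 of 2 replicates of a genotype and a DNA part (L or S). Per the labels, both replicates of a group point to the same list, so the 4 lists could not be split by replicate. The genome build was mm10, per the submitters' processing notes. The caller of the modified bases and its version, the aligner, the filters and the way the replicates were joined are not given in the sources used here.

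Each line of a deposited list is a single called adenine with its chromosome, position, strand and 41-base context. The deposited score of each call, in which 20 was the lowest value, was read as a modification score on the caller's own scale, since no source used here states the scale. The deposited IPD ratio is a linear ratio of the observed inter-pulse duration to a predicted one. The deposited coverage is a signal without normalization, and it counts the sequencing passes or reads at the base, which need not come from different molecules. The deposited modified fraction and its bounds were given at coverage of 11 or more only, and the deposited identification score states the fit to N6-methyladenine. The lists hold called bases alone, so the depth at other bases is unknown, and no limit can be set for a gene without a site. The values were used as the authors deposited them, with no filter.

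Lists were compared within a part (KO with WT) and within a genotype (L with S). Shares have exact Clopper-Pearson intervals at 95%, which treat sites as independent and leave out clustering. Differences and ratios have percentile intervals from 1000 bootstrap resamples of 100 kb blocks of the genome, drawn for the 4 lists together, so that sites of a block stay together. Such an interval covers counting error and clustering, and no p-value between genotypes was computed. A KO minus WT difference in S was set against that in L in the same resamples. For the coverage ratios at shared bases, only the blocks that hold such bases were drawn. Shared sites had the same position and strand, and a local level was taken from 20 shifts of 1 to 20 kb. These shifts keep neither the called base nor the phase of tandem repeats. Local background was the share among the other adenines of the same contexts.

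Genes came from a RefSeq gene table of assembly GRCm38.p6, the same chromosome coordinates as mm10, with 49939 genes on chromosomes 1 to 19, X and Y. It was used from gene start to gene end without strand or exons, so a site is said to lie in a gene and not in an exon or intron. The 10 gene lists were fixed before the data were examined. The KO to WT ratio of a list's sites (plus 0.5) was set against 10000 random lists of as many genes matched on length deciles, with 5 kb on each side of each gene. A site near several genes of a list was counted for each of them. Lists of clustered genes can count sites again more often than random lists do, and the percentiles were not corrected for this. Genes in the text were named by a rule fixed before the data were examined. Alkbh1 came first. Then came, for each part, the 10 genes with the largest excess of sites in KO and the 10 with the largest excess in WT, among genes with 3 or more sites in the 2 lists together. Ties were broken by sites per kb and then by symbol, and a gene that shared sites with a higher ranked one was skipped. Members of a fixed list were eligible at 2 or more sites over the 4 lists, at most 4 per list. Some genes that the rule took are not reported here. The 5 richest windows, the 3 sites with the highest score in each list and at most 5 sites called in the 4 lists were also eligible.

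A context was called satellite-like when it shared 3 or more 12-base words with a 234-base consensus of the mouse major satellite, written from textbook knowledge. Shuffled contexts passed this in at most 2 cases per list, against 324 to 510 of the real ones. Adenines of the repeat unit were assigned by the best match of a context to the unit, with 33 or more of 41 bases equal.

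On simulated data built from the real blocks of the S lists (7142 and 3370 sites), the bootstrap interval held the true difference in AG share in 57 of 60 runs at a difference of 0 and in 57 of 60 at 5 points. At 5 points it excluded 0 in 60 of 60. Of 200 planted shared positions 200 were found, which checks the exact matching alone. For the gene lists in S, 200 genes were drawn among those with a site, and both genotypes had the same mean. Such a list with 3-fold more sites in KO left the central 95% in 20 of 20 runs, and a list without change in 0 of 20. No fixed list is of that size, and most members of the fixed lists held no site, so these runs do not give their power. With sites drawn by gene length, the 2 lists of 2073 and 2512 genes left the central 95% at a 3-fold change in 40 of 40 runs in each part. For the 2512 X-linked genes these runs expected 119 WT sites in L and 224 in S. The real list held 53 and 72, so its power is overstated. The 8 lists of 10 to 31 genes did so in 2 to 9 of 40 in L and in 3 to 10 of 40 in S, against 0 to 5 and 0 to 4 without change.

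Alternatives set before the data were examined were a score of 30 or more, coverage of 25 or more, coverage of 100 or less, coverage matched in bins of 5, 1 site per 1 kb, leaving out windows of 100 kb with 10 or more sites, chromosomes 1 to 19 and X, L and S merged, a modified fraction of 0.5 or more, wider tolerances for shared sites and gene bodies without flanks. Others were added later and are named with their effect in the closing section. The share of sites in exons and in repeats was not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.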

Results

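The series measured adenine modification in DNA bound to H2A.X, a histone variant known for its phosphorylation at DNA breaks. The cells were mouse TT2 embryonic stem (ES) cells, a line from a C57BL/6 by CBA cross, grown without feeder cells and used at passage 5 to 10. Chromatin was immunoprecipitated without crosslinking, the DNA was split into a long part (L) and a short part (S), and each part was sequenced on single molecules. In this sequencing the polymerase slows at some modified bases, and the inter-pulse duration (IPD) ratio gives the slowing at each base relative to the value predicted for unmodified DNA. Wild-type (WT) cells and cells with a knockout (KO) of Alkbh1, which encodes a dioxygenase of the AlkB family described as an N6-methyladenine demethylase, were compared in both parts. The 8 samples formed 4 groups of 2 replicates, and the values came as 1 list of called adenines per group with both replicates together. The difference between genotypes therefore has no replicate check. Bootstrap intervals below cover counting error and the clustering of sites only. Exact intervals treat sites as independent, so they cover counting error alone and are too narrow where sites cluster.

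The lists held 3862 sites in WT L, 3044 in KO L, 7142 in WT S and 3370 in KO S. Median coverage at the called bases was 11 in both L lists, 14 in WT S and 12 in KO S, from a lowest value of 6 to highest values of 5513 to 10725. Coverage reached 25 at 11.9% of sites in WT L, 14.1% in KO L, 18.6% in WT S and 14.99% in KO S. The score of a call, in which 20 was the lowest value in each list, had a median of 24 in WT L, KO L and KO S and of 25 in WT S. A second score, which states how well the kinetics fitted N6-methyladenine in particular, had a median of 7 or 8 and reached 20 at 459, 403, 1157 and 490 sites of WT L, KO L, WT S and KO S. The plus and minus strands held 1918 and 1944 sites in WT L, 1502 and 1542 in KO L, 3457 and 3685 in WT S and 1619 and 1751 in KO S, and no list held a site on the mitochondrial genome.

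The first comparison asked whether the loss of Alkbh1 changed how many adenines were called. KO lists were shorter than WT lists in both parts. KO held 0.788 times as many sites as WT in L (95% bootstrap interval 0.741 to 0.832) and 0.472 times as many in S (0.446 to 0.497). Coverage at the 141 bases called in both L lists was 0.969 times as high in KO as in WT (median, 0.939 to 1.00), and at the 161 bases called in both S lists it was 0.605 times as high (0.535 to 0.658). Each interval came from resampling only the blocks with shared bases, 8 in L and 9 in S, which is few. Of these shared bases 121 and 147 had a satellite repeat context, so they do not give the depth over the rest of the genome. The depth at bases that were not called is not listed, and the numbers of sites were not corrected for depth.

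Alkbh1 itself (chromosome 12, 87428077 to 87443839, mm10) held no called site in any of the 4 lists, within the gene or 5 kb on each side. This does not test the knockout, because a list of modified bases does not show whether the gene is intact.

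The share of sites on chromosome X did not differ between the genotypes beyond its error. The share was 2.30% in WT L (89 sites, exact 95% interval 1.85% to 2.83%) and 2.60% in KO L (79 sites, 2.06% to 3.22%). In S it was 2.31% in WT (165 sites, 1.97% to 2.69%) and 2.28% in KO (77 sites, 1.81% to 2.85%). KO minus WT was 0.29 percentage points in L (-0.44 to 1.08) and -0.03 in S (-0.72 to 0.63). L minus S was -0.01 points in WT (-0.70 to 0.66) and 0.31 in KO (-0.50 to 1.12). Density on chromosome X, without the densest windows, was 0.417, 0.476, 0.400 and 0.410 times the median over autosomes in WT L, KO L, WT S and KO S. Chromosome Y carried 36, 31, 71 and 37 sites in the same order. TT2 is a male line, with a single chromosome X. Chromosome 11 had the highest density of the autosomes in each list, from 16.5 sites per 10 Mb in KO L to 37.2 in WT S.

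**Figure D1:**
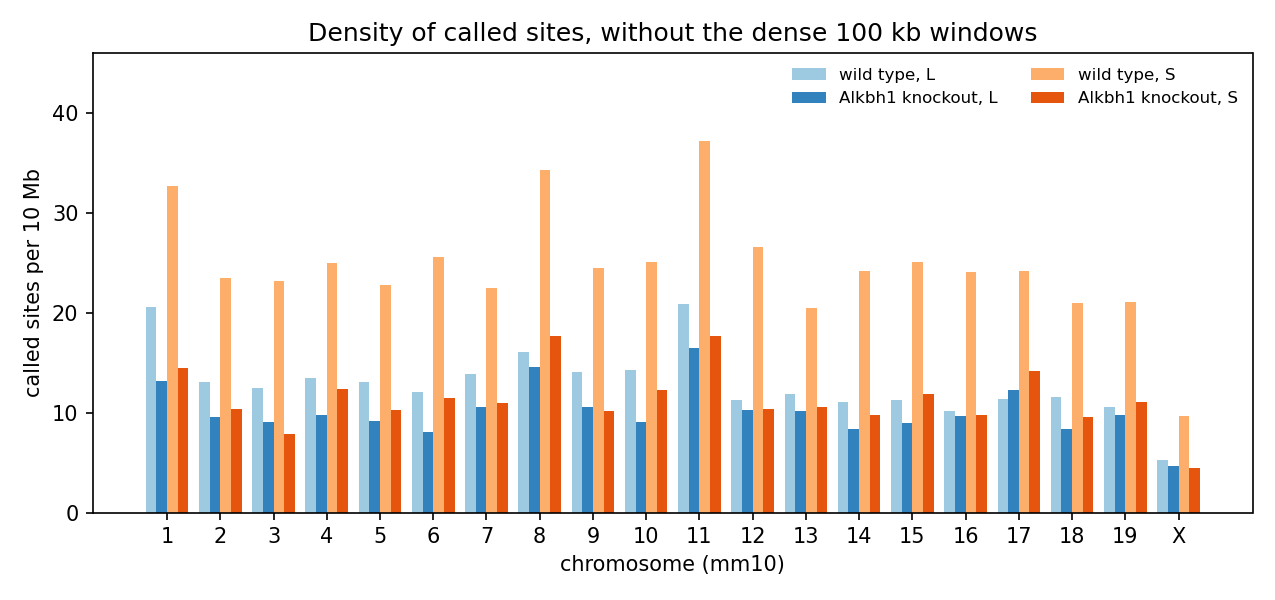
Called sites per 10 Mb (vertical axis) on each chromosome of mm10 (horizontal axis) in the 4 lists, 1 bar per list, without the 100 kb windows that held 10 or more sites in any list. Chromosome X lies below each autosome in each list, at 5.21 (WT L), 4.63 (KO L), 9.67 (WT S) and 4.51 (KO S) sites per 10 Mb.

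Within genes, the largest differences between genotypes were a few sites per gene, and the genes named differed between L and S with few exceptions. In L, Mtcl1, which encodes a microtubule crosslinking factor (chromosome 17, 66336980 to 66449806), went from 0 sites in WT to 7 in KO, 5 of them within 1 kb. Dlgap2, which encodes a postsynaptic scaffold protein (chromosome 8, 14095776 to 14853426), had 0 sites in WT and 7 in KO in L and 1 and 5 in S, and was named in both parts. Gm30679, Gm46174, Gm16497, Gm40032, the potassium channel gene Kcnc1, Gm31108, Syndig1 and Tmcc1 each had 0 sites in WT and 4 in KO. In the other direction, Wdr26 (chromosome 1, 181173226 to 181220921) had 6 sites in WT L and 0 in KO L, which spanned 256 bases. Atp8a2, which encodes a phospholipid flippase, had 6 and 0, and B230307C23Rik and Dpp6 each had 5 and 0. Csmd1 (chromosome 8, 15892538 to 17535385) had 6 sites in WT and 1 in KO in L and 7 and 0 in S. Gm8613, the thyroid hormone receptor gene Thra, the hedgehog pathway transcription factor gene Gli2, Rasgrf2 and Brinp3 each had 4 and 0, and Rasgrf2 had 0 and 1 in S.

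In S, Garre1 (chromosome 7, 34236707 to 34313554) had 0 sites in WT and 6 in KO within 138 bases, and Rasgef1b had 0 and 5 within 92 bases. Cacna1a, which encodes a calcium channel subunit (chromosome 8, 84338631 to 84640251), had 0 and 5 in S and 1 and 3 in L. Nrg1, which encodes neuregulin 1, had 1 and 6 in S and 0 and 2 in L, while Zfp335, Crim1, Tiam2, Nubpl and Atrnl1 each had 0 and 4 in S, and Nubpl had 1 and 0 in L. More sites in WT were seen at larger differences, in a list with 7142 sites against 3370. The T cell receptor alpha locus Tcra (chromosome 14, 52427967 to 54224198) had 13 sites in WT S and 0 in KO S. The immunoglobulin kappa locus Igk had 12 and 2 in S, against 5 and 5 in L. Pcnx2, Inpp4b and Auts2 had 8 and 0, where Auts2 had 1 and 4 in L, the other way. Sh3d19 had 7 and 0, and the transcription factor gene Sox5 had 8 and 1. Arntl, a transcription factor gene of the circadian clock (chromosome 7, 113178471 to 113314126), had 7 sites in WT S and 0 in KO S, against 0 and 1 in L. The 7 sites lay within 15 bases and had a median IPD ratio of 4.39.

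Of the 10 genes that the naming rule took per part and direction, the other part moved the same way for 2 (more in KO, L), 4 (more in WT, L), 4 (more in KO, S) and 5 (more in WT, S). It held no site at all in 8, 5, 5 and 1 of them. All sites of the leading genotype lay within 1 kb in 5, 3, 5 and 2 of the 10 genes. The rule ranked by number of sites, which favours long genes, and 4, 6, 7 and 9 of the 10 were over 100 kb. No chance level for the largest differences is given here. Genes with a site in both genotypes numbered 221 in L and 339 in S, against 175 and 304 that genes of the same length would give if the genotypes drew them independently.

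The fixed gene lists held few sites, and no group other than the pluripotency genes in S stood outside the central 95% of random lists matched on gene length. The numbers of a list count a site for each listed gene that it lies in or within 5 kb of. The 26 pluripotency genes with 5 kb on each side held 1 site in WT L and 0 in KO L (percentile 22.1 of the KO to WT ratio), and 0 in WT S and 3 in KO S (98.9). Tcl1, which encodes an AKT cofactor (chromosome 12, 105216753 to 105222737), held 2 of these 3. The 25 imprinted genes held 3 and 1 sites in L (27.3) and 6 and 0 in S (4.16), with 2 sites each in WT S in Peg10 and Rian. The 31 lineage genes held 3 and 2 in L (46.2) and 5 and 5 in S (78.6). Runx1, a blood lineage transcription factor gene, had 1 site in WT S and 3 in KO S, and Kdr had 2 in WT L and 1 in WT S. The 18 DNA damage response genes held 1 and 3 sites in L (84.3) and 9 and 3 in S (40.02). Atm, the kinase gene of the break response, had 0 and 2 in L and 3 and 1 in S. The 24 genes of DNA and adenine methylation enzymes held 3 and 2 in L (45.7) and 6 and 2 in S (40.4), and Fto held 4 over the 4 lists. The 15 genes active at the two-cell stage held 0 and 0 in L (51.7) and 2 and 0 in S (6.62), both in Tcstv1. The 10 genes of the X inactivation centre held 0 and 1 in each part (86.2 in L and 91.6 in S). The 10 fibroblast genes held none in any list, which left their percentiles at 55.0 and 65.2. Among 2512 X-linked genes, WT and KO held 53 and 31 sites in L (3.14) and 72 and 37 in S (81.1). The 2073 chemosensory receptor genes held 39 and 22 in L (10.2) and 67 and 29 in S (54.0), with 6 sites in WT S in Olfr1364. With 10 lists and 2 parts, a single value outside the central 95% is what chance alone would give on average, and the pluripotency value rests on 3 sites. In simulations a 3-fold change in KO left the central 95% in 2 to 10 of 40 runs for lists of 31 genes or fewer, so their lack of difference says little.

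Gene bodies held a slightly smaller share of sites in KO than in WT, and the interval of this difference depended on the setting. The share was 47.8% in WT L (exact interval 46.2% to 49.4%), 44.8% in KO L (43.0% to 46.6%), 48.2% in WT S (47.1% to 49.4%) and 45.4% in KO S (43.7% to 47.1%). With clustering the intervals were wider, for example 43.3% to 52.1% in WT L and 39.7% to 50.1% in KO L (bootstrap). These shares count sites on unplaced contigs, which have no genes in the table. On chromosomes 1 to 19 and X, of which genes cover 47.2%, they were 50.7%, 47.8%, 50.6% and 48.4% in the same order. KO minus WT was -3.05 points in L (bootstrap interval -5.68 to -0.31) and -2.84 in S (-5.32 to -0.37). Protein-coding genes held 39.9% of sites in WT L and 37.02% in KO L, and 40.5% and 37.8% in S, while lncRNA genes held 7.77%, 7.79%, 7.87% and 8.28%. Of 12 other settings with an interval, the interval excluded 0 in none in L and in 7 in S. Without the densest windows the difference was -2.08 points in L (-4.97 to 0.62) and -1.51 in S (-3.88 to 1.08). At a score of 30 or more the value in L was 0.41 (-4.22 to 6.13). Sites in satellite repeats, few of which lay in genes, made up more of the KO lists (10.6% against 8.65% in L, 9.97% against 7.14% in S). Without them the difference was -2.30 in L (-5.19 to 0.57) and -1.69 in S (-4.17 to 0.84).

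The base after the called adenine differed between genotypes. An AG context was carried by 21.2% of sites in WT L (exact interval 19.95% to 22.6%), 23.6% in KO L (22.1% to 25.1%), 21.1% in WT S (20.2% to 22.1%) and 27.6% in KO S (26.1% to 29.1%). KO minus WT was 2.32 points in L (bootstrap interval 0.13 to 4.50) and 6.47 in S (4.66 to 8.29). Among the other adenines of the same 41-base contexts, a local background, the AG share was 23.3%, 23.1%, 22.7% and 23.8%. Set against that background, KO minus WT was 2.54 points in L (0.22 to 4.70) and 5.35 in S (3.62 to 7.19). The share was higher in KO on 14 of 20 chromosomes in L and on 19 of 20 in S. In L the interval included 0 in 11 of 12 other settings, for example with coverage matched between the genotypes (2.10 points, -0.31 to 4.29). In S it excluded 0 in 11 of 12, and the difference was 3.98 points at a second score of 20 or more, where the interval included 0 (-0.87 to 9.11).

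In S the contexts that gained were GAG, from 5.95% of WT to 8.55% of KO sites, CAG from 7.21% to 9.14%, AAG from 4.89% to 6.05%, GAC from 2.94% to 4.04% and TAG from 3.08% to 3.86%. Those that lost were AAA, from 11.7% to 9.58%, GAA from 8.08% to 6.47%, TAA from 7.27% to 5.93% and TAT from 7.18% to 6.11%. In L the intervals excluded 0 for AAG (4.79% to 6.11%) and TAC (2.98% to 3.81%), which gained, and for CAT (10.4% to 8.38%), GAT (4.48% to 3.52%) and TAT (7.90% to 6.47%), which lost. The 16 contexts in 2 parts were not adjusted for their number. AGG made up 6.84% of sites in WT L, 7.13% in KO L, 6.45% in WT S and 9.23% in KO S, which was 1.21, 1.23, 1.15 and 1.55 times the share among the other adenines. GAGG made up 2.30%, 2.37%, 2.20% and 2.97% in the same order, or 1.89, 1.87, 1.65 and 2.17 times that background.

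**Figure D2:**
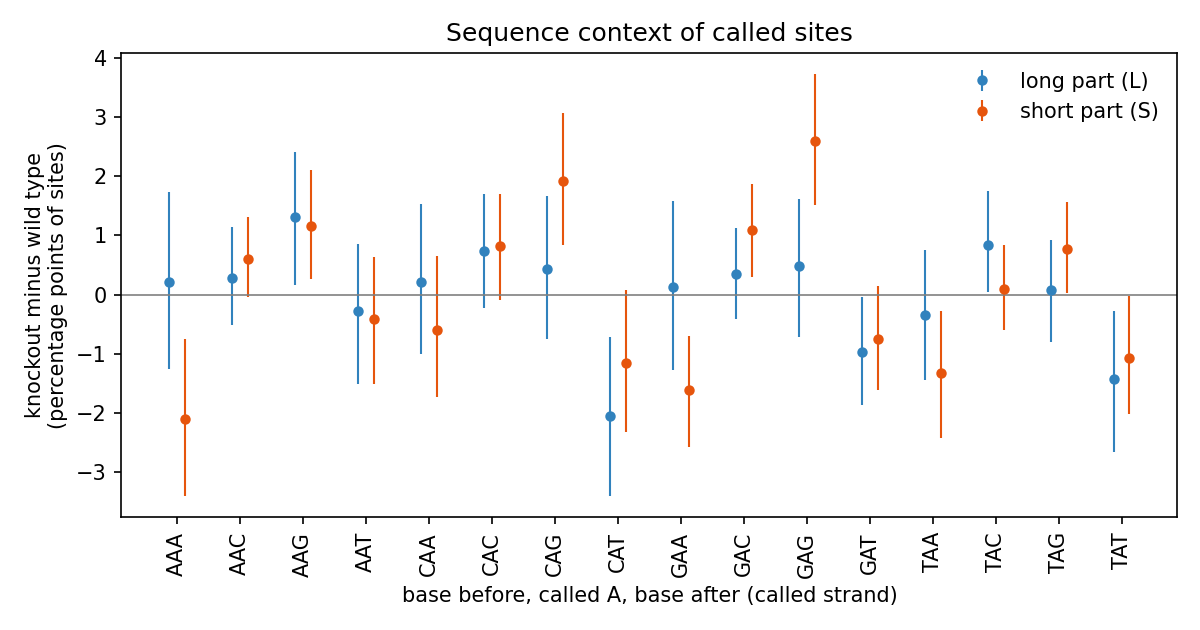
Difference between KO and WT (vertical axis, percentage points of sites) in the share of each 3-base context of the called adenine (horizontal axis), for L and S. Points are the differences and bars their 95% bootstrap intervals over 100 kb blocks, and the largest gain is that of GAG in S, at 2.60 points (1.52 to 3.73).

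The size of the differences in kinetic signal, and the sign of some, depended on the setting. The median IPD ratio was 2.56 in WT L, 2.57 in KO L, 2.56 in WT S and 2.66 in KO S. KO minus WT was 0.01 in L (-0.04 to 0.06) and 0.10 in S (0.05 to 0.15). In S the value was 0.02 with coverage matched (-0.03 to 0.08), -0.05 at coverage of 25 or more and 0.13 without satellite contexts (0.07 to 0.17). The estimated modified fraction, given at sites with coverage of 11 or more, had a median of 65.8% in WT L (bootstrap interval 57.6% to 73.0%), 61.3% in KO L (54.1% to 68.9%), 68.0% in WT S (63.3% to 72.1%) and 71.1% in KO S (64.4% to 78.4%). KO minus WT was -4.5 points in L (-7.5 to -1.0) and 3.1 in S (-0.4 to 7.4). At coverage of 25 or more the value was 0.1 in L and -3.4 in S (-6.9 to -0.5), with the opposite sign in both parts. With coverage matched it was -1.65 in L (-5.6 to 2.8) and 1.6 in S (-2.4 to 5.6), and the interval in L excluded 0 in 4 of 12 other settings. Without satellite contexts it was -3.25 in L (-6.5 to -0.1) and 6.6 in S (3.4 to 9.6).

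The last comparison asked how often a called base recurred in another list. Of the KO L sites, 141 were called at the same base in WT L (4.63%, exact interval 3.91% to 5.44%), against a mean of 0.02% after shifting the sites by 1 to 20 kb. The shifts land on any base and lose the phase of tandem repeats. A level near 0 was thus largely fixed in advance, and it gives no chance level within satellite repeats. Of the KO S sites, 161 were called in WT S (4.78%, 4.08% to 5.55%). Of the WT S sites, 170 were called in WT L (2.38%, 2.04% to 2.76%), and of the KO S sites, 120 were called in KO L (3.56%, 2.96% to 4.24%).

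The shared bases lay mostly in satellite repeats. Of the 8 windows of 100 kb with 10 or more sites in any list, 6 held sequence like the mouse major satellite, the tandem repeat of pericentromeric heterochromatin. The richest were the unplaced contig JH584304, with 128 sites in WT L between positions 14066 and 99493, and chromosome 9 from 3000135 to 3038205, with 97 sites in WT L, 109 in KO L, 195 in WT S and 120 in KO S. Chromosome 14 from 19415767 to 19419591 held 55, 49, 63 and 50, and chromosome 2 from 98662211 to 98667176 held 24, 35, 28 and 26. Inside the 8 windows 37.5% of KO L sites were called in WT L, 42.7% of KO S sites in WT S, 28.7% of WT S sites in WT L and 31.7% of KO S sites in KO L. Elsewhere 7 of 2687, 9 of 3014, 6 of 6571 and 7 of 3014 sites were shared.

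**Figure D3:**
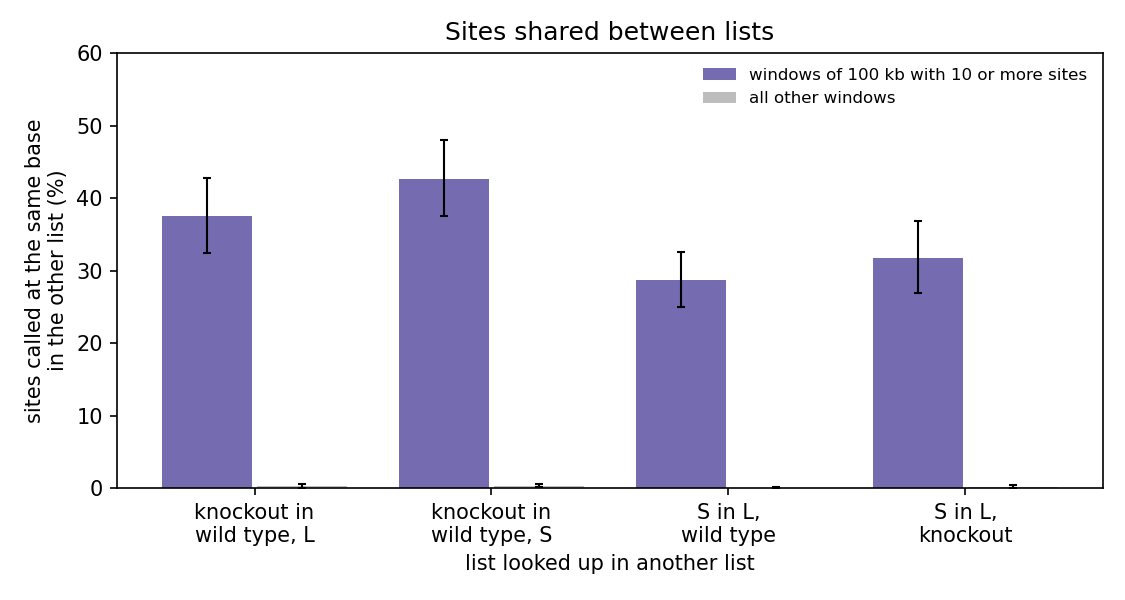
Share of the sites of 1 list called at the same base and strand in another (vertical axis, percent) for 4 pairs of lists (horizontal axis), inside the 8 windows of 100 kb with 10 or more sites and in the other windows. Bars give the share and lines its exact 95% interval, and the share is 28.7% to 42.7% inside these windows and 0.09% to 0.30% elsewhere.

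Contexts like the satellite made up 8.65% of sites in WT L, 10.6% in KO L, 7.14% in WT S and 9.97% in KO S. Their median coverage was 88.5, 85, 117.5 and 85.5, against 10, 10, 14 and 11 at the other sites. Their median IPD ratio was 1.85, 1.88, 1.83 and 1.88, against 2.65, 2.67, 2.63 and 2.76, and their median modified fraction was 28.0%, 28.9%, 28.8% and 31.2%, against 73.5%, 70.2%, 72.5% and 79.1%. Both values fell with coverage among called sites, and at like coverage most of this contrast was gone. At coverage of 25 to 49 the median IPD ratio of satellite sites was 2.04, 2.20, 2.22 and 2.05, against 2.12, 2.20, 2.06 and 2.11 at the others. The interval of the difference included 0 in each list there and at coverage of 50 or more. For the modified fraction it excluded 0 in WT L at coverage of 25 to 49 alone (-10.1 points, -47.5 to -4.45). Within genes lay 1.57% to 2.68% of satellite sites and 49.9% to 52.2% of the others.

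The site with the highest score in each list was the same base, chromosome 14 position 19417726 on the minus strand, outside any annotated gene. Its context was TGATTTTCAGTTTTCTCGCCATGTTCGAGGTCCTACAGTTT, with the called adenine at base 21. Its modified fraction was 81.9% in WT L (72.2% to 90%, as given with the call, at coverage 384), 85.0% in KO L (76.1% to 94.0%, 407), 91.8% in WT S (84.4% to 97.8%, 569) and 85.2% in KO S (77.0% to 94.6%, 391). At chromosome 2 position 98667009 on the plus strand the fraction was 22.3%, 19.5%, 23.1% and 19.2% at coverage of 4427 to 6222. Chromosome 9 position 35305292 on the plus strand, inside Gm33838, had 63.6%, 61.4%, 64.1% and 66.3%. Each of these bases had a satellite context, and coverage far above the medians of 10 to 14 at sites without one. Whether reads of other repeat copies were placed there was not tested. Each fraction may thus average over copies of the repeat and need not describe a single locus. In all, 68 bases were called in the 4 lists, of which 63 lay in the 8 windows and 58 had a satellite context. A single one lay outside the windows and had no satellite context, at chromosome 6 position 103649294 on the plus strand inside Chl1, which encodes a neural cell adhesion molecule. It was picked out after its values were seen. Its modified fraction was 47.7%, 45.7%, 44.8% and 63.4% at coverage of 114, 115, 237 and 84.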

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

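Coverage matching was a setting fixed before the data were examined, and its use as a test here was chosen after the results were seen. So were the tests by satellite repeats, by the libraries of 1 genotype and of sequencing depth. The tests by GC content and by runs of A were added after the first results, and written before their own values were seen.

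The difference between KO and WT was not the same in L and S for 5 measures in the deposited lists, as the interval of the difference between the parts excluded no difference. The KO to WT ratio of site numbers in S was 0.599 times that in L (0.557 to 0.641). The KO minus WT difference in AG share was 4.15 percentage points higher in S than in L (1.14 to 7.02), that in the background AG share was 1.33 higher (0.19 to 2.39), and set against this background the AG gap was 2.81 (-0.09 to 5.66), which included 0. Over 12 other settings the AG gap ran from -1.30 (-8.91 to 6.60, second score of 20 or more) to 5.13 (without satellite contexts), and its interval included 0 in 4, among them a score of 30 or more (1.11) and coverage of 25 or more (1.30). Set against the background, the AG gap ran from -3.69 to 3.69 over the same 12 settings, and its interval included 0 in 8. The KO minus WT difference in the median IPD ratio was 0.09 higher (0.02 to 0.16), and that in the median modified fraction was 7.6 points higher (2.5 to 12.1). With coverage matched these 2 gaps were 0 (-0.07 to 0.10) and 3.25 (-2.40 to 8.90), and at coverage of 25 or more -0.06 (-0.14 to 0.03) and -3.5 (-8.3 to 1.4), with intervals that included 0, so coverage stays open as their cause. Over 12 other settings the interval excluded 0 in 4 for the IPD gap and in 7 for the modified fraction gap, which ran up to 0.16 (second score of 20 or more) and 9.85 (without satellite contexts). The differences in the shares on chromosome X and in gene bodies were apart by -0.32 points (-1.30 to 0.72) and 0.21 points (-3.50 to 3.67), within their intervals.

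The shorter KO lists may come from sequencing depth, from fewer modified bases or from other differences between the libraries, such as the DNA recovered with H2A.X. All samples were immunoprecipitated, so the recovered DNA could not be set against input DNA. In S, coverage at bases called in both genotypes was 0.605 times as high in KO (0.535 to 0.658), next to a site ratio of 0.472. In L it was 0.969 times as high (0.939 to 1.00), next to a site ratio of 0.788, so a depth that fell in proportion to the sites was not seen at these bases. The shared bases lay mostly in 6 satellite windows, and the intervals of their coverage ratios rest on 8 blocks in L and 9 in S. How the number of calls rises with depth is unknown, so depth stays open in both parts. A loss or gain of modified bases through Alkbh1 was not separated from the library, with 1 list per group.

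The higher AG share in KO S was not fully accounted for by several technical features. KO S differed from WT S in base composition. GC of the contexts was 1.47 points higher (0.96 to 1.97), and the share of sites in runs of 4 or more A was 3.40 points lower (-4.73 to -2.08). Both measures take in the base after the called adenine, so an AG context by itself moves them. Of the 4 settings below, matching on GC left the smallest difference. Composition may account for part of the AG difference, but this overlap with the AG share cannot be told apart from it. The difference was 6.41 points with coverage matched (4.24 to 8.55), 4.81 with GC of the contexts matched (2.71 to 6.96), 6.86 without satellite contexts (4.88 to 8.91) and 6.06 without runs of 4 or more A (4.05 to 7.92), against 6.47 as deposited. In L the same settings gave 2.10, 1.75, 1.73 and 2.13 points, each with an interval that included 0, so nothing can be excluded there. The L and S lists of KO differed from each other by 4.04 points and those of WT by 0.10, so the difference between the libraries of KO was larger than the difference between genotypes in L (2.32) and smaller than that in S. A difference between libraries and an effect of Alkbh1 on the sequence context cannot be told apart, for want of lists per replicate.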

How the results depend on the processing

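The second score of 20 or more, the settings without satellite contexts or runs of A, the 2 kb flanks and the set-against-background AG share were chosen after seeing the data, and so was matching on GC. Of 248 values under other settings for 20 results, 162 stayed within the interval or count range of the deposited value, 82 moved out of it and 4 turned a direction whose own interval excluded no effect. In all 23 values had the opposite sign, 19 of them for a result whose interval included no effect. The cause was not tested. The KO to WT ratio of site numbers stayed below 1 under the 11 settings run in each part, and the AG difference stayed above 0 under 13 in each part (1.67 to 5.45 in L and 3.98 to 6.86 in S). Values below are KO minus WT unless said otherwise, in percentage points for shares and fractions.

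Of results whose interval excluded 0, the direction turned at a score of 30 or more for gene bodies in L (0.41) and the IPD ratio in S (-0.06), and at coverage of 25 or more for the modified fraction in L (0.1) and the IPD ratio in S (-0.05). At a score of 30 or more the site ratio was 0.914 in L and 0.421 in S. In S the chromosome X share was -0.82, the modified fraction -0.55 and the gene body share -5.92, and chromosome X in KO L minus S was 1.29. Sharing was 15.4% (KO in WT, L), 13.7% (KO in WT, S), 6.10% (S in L, WT) and 10.9% (S in L, KO). At coverage of 25 or more the site ratio was 0.933 and 0.379, chromosome X in L -0.85, AG in L 5.45, the modified fraction in S -3.4, gene bodies in S -10.1 and chromosome X in KO L minus S -0.76. Sharing in the same order was 31.4%, 29.5%, 11.9% and 22.6%. At a second score of 20 or more the site ratio was 0.878 and 0.424, the IPD ratio in L -0.10, AG 5.28 in L and 3.98 in S, chromosome X in S 0.73, the modified fraction in S -5.4, gene bodies in S -5.89 and chromosome X in KO L minus S -1.32. Sharing was 19.1%, 15.3%, 6.57% and 13.7%. With a modified fraction of 0.5 or more the site ratio in S was 0.394.

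Sharing in that order was 1.59%, 0.996%, 0.615% and 1.15% at coverage of 100 or less, 1.35%, 1.66%, 0.709% and 1.29% with 1 site per 1 kb, and 0.261%, 0.299%, 0.0913% and 0.232% without rich windows. It was 3.06%, 3.45%, 1.41% and 2.498% on chromosomes 1 to 19 and X, 1.65%, 1.27%, 0.529% and 1.04% at a modified fraction of 0.5 or more, 0.735%, 0.461%, 0.332% and 0.428% without satellite contexts, and 2.51%, 1.45%, 1.84% and 1.83% with coverage matched. Within 10 bases on either strand it was 6.54%, 6.32%, 3.37% and 4.87%, and within 100 bases 9.13%, 8.93%, 5.36% and 7.48%. With coverage matched the IPD ratio in S was 0.02. With L and S merged the site ratio was 0.581, the modified fraction -0.4 beside that of L, and AG 4.64. The number of gene lists outside the central 95% of random lists, 0 in L and 1 in S, became 1 in L with 1 site per 1 kb and with coverage matched. It became 0 in S at a modified fraction of 0.5 or more, without runs of A and with L and S merged.

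An interval can also come to include 0 while the value stays in range. Of 12 settings with an interval, it excluded 0 in 1 for AG in L (1 site per 1 kb, 2.66, 0.36 to 5.02), in 11 for AG in S, in 0 for gene bodies in L and in 7 for gene bodies in S. It did so in 4 for the modified fraction in L and in 7 for the IPD ratio in S. For the modified fraction in S, whose own interval included 0, it excluded 0 in 7, among them coverage of 25 or more (-6.9 to -0.5), where the sign was opposite. No paired analysis was possible because each list joins both replicates, and for the same reason no replicate could be left out. Exon share, repeat share and contexts found once in the genome were not run, since no genome sequence or exon annotation was used here. Gene bodies with 2 kb upstream were not run because the gene table gives no strand, and 2 kb on each side was run in its place (-2.52 in L and -2.54 in S). Coverage matching makes site numbers equal and gives no ratio. Sites with coverage near the median of 11 to 14 carry few passes, which limits single sites most.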

Other observations

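In this part the tests of high coverage by KO sites and of the adenines of the repeat unit were written before their values were seen, and the test at matched coverage was chosen after.

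Site density was uneven between autosomes, and whether the pattern agrees between lists was not tested. Chromosomes 8 and 11, gains of which are well known in cultured mouse ES cells, held 16.1 and 20.9 sites per 10 Mb in WT L, 14.5 and 16.5 in KO L, 34.3 and 37.2 in WT S, and 17.6 and 17.7 in KO S, without the 8 richest windows. The medians over autosomes were 12.5, 9.72, 24.1 and 11.01. Chromosome 1 held 20.6 and 32.7 in WT L and WT S, against 13.2 and 14.5 in KO L and KO S, and chromosome 17 held 11.4 and 24.1 against 12.2 and 14.1. These chromosomes were picked out after their values were seen, and copy number and gene density were not analysed here.

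Called sites often came in small groups. Outside the 8 richest windows, 17.1% of sites in WT L, 19.3% in KO L, 24.7% in WT S and 22.1% in KO S had another site of the same list within 150 bases, about the length of DNA around a nucleosome core. Within 10 bases the shares were 5.69%, 5.32%, 8.70% and 5.54%. Few sites had a call nearby in another list, though more than after shifts of 1 to 20 kb. Within 100 bases on either strand, 0.63% of KO L sites outside these windows had a WT L site, against 0.043% after shifts. Of WT S sites 0.24% had a WT L site, against 0.024%. These shares are over all sites there, satellite contexts included, and the return of groups was not tested. Of the 7 KO L sites there called at the same base in WT L, 2 had no satellite context. Of the 6 such WT S sites called in WT L, 1 had none. The shifts lose the phase of tandem repeats, so the excess over them does not show that calls outside satellites recur.

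Across the 68 bases called in the 4 lists, the highest IPD ratio of a base was 1.18 times its lowest (median over bases). Within the satellite unit, sites were spread unevenly over the 148 adenines of both strands. The 10 most used adenines held 54.0% of the sites placed on a unit adenine in WT L, 49.8% in KO L, 51.3% in WT S and 57.1% in KO S.

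Recurrence in satellite windows may reflect fixed adenines of the repeat unit, as site numbers per unit adenine in the chromosome 9 window and in the JH584304 contig rose together, with a Spearman rho of 0.517 in WT L and 0.465 in WT S, and of 0.405 in KO L and 0.524 in KO S (Pearson r 0.398, 0.479, 0.149 and 0.431; permutation p for rho 1e-05 in each, the smallest that the permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over 8 correlations). These are correlations across adenines, which are not independent replicates, and the windows carry nearly the same sequence. Whether reads of the repeat were placed in the right window was not tested. Both windows may thus hold reads of the same pool of repeat copies, from which a rho above 0 would follow. A fixed modification, a fixed sequence effect on the polymerase and such placing of reads all remain open. High coverage in both lists could not be weighed, since KO sites at coverage of 50 or more outside satellites and rich windows recurred in 1 of 9 (11.1%) in L and 1 of 3 (33.3%) in S. At coverage of 25 to 49, matched in bins of 5, satellite sites recurred in 15.6% (KO in WT, L), 25.5% (KO in WT, S), 16.2% (S in L, WT) and 19.1% (S in L, KO), and the others in 0 of 32, 47, 74 and 47 (1 of 89, 0 of 172, 0 of 772 and 0 of 172 before matching). Here the lower bound of satellite sites was the smaller of the exact one and that over blocks. The exact upper bound of the others lay below it for KO in WT, S (7.55% and 10.9%, over blocks) and S in L, WT (4.86% and 8.67%, exact). These 2 satellite shares rest on 12 recurring sites each, and their block intervals on 4 and 5 blocks. The values argue, on this small base, against coverage in the first list alone for these 2 pairs. The other 2 pairs and coverage in the second list stay open.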
